A study of Mus musculus with 3 samples.

How the data were processed

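RNA-seq of polyadenylated RNA was deposited for 3 libraries of C2C12 cells, with 1 library in each group: mock-transfected cells in growth medium, cells labelled shKSRP in growth medium, and mock-transfected cells labelled DM + BMP2. Per the labels' protocols, RNA was purified with oligo(dT) beads in 2 rounds, fragments of 250 ± 25 bp were taken from a gel, libraries had 18 cycles of PCR, and sequencing was on an Illumina HiSeq 2000. PCR copies were not marked by molecular identifiers, so intervals on the values cover counting and assignment error only. Whether the protocol marks strand is not given in the sources used here.

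For each library the authors deposited a Cufflinks transcript file with FPKM, which is fragments per kilobase of transcript scaled to the mapped fragments, and the bounds of its 95% interval, per the file headers and attributes. The authors' files also carry a score per transcript, which Cufflinks sets relative to the most abundant transcript of the locus, as deposited, and which was not used in any comparison. The submitters' processing notes name CASAVA 1.8, Bowtie 0.12.7, TopHat 1.4.1, Cufflinks 1.3.0 and the mm9 build, and their roles and settings are not given in the sources used here. Each library was assembled on its own. Each file lists the same 28702 RefSeq transcripts, of which 14649 in mock, 14694 in the library labelled shKSRP and 14876 in the BMP2 library were above 0, besides 17240, 14761 and 17278 transcripts assembled from the library's own reads. An assembled transcript can take fragments from a RefSeq transcript in 1 library and not in another, which moves FPKM between transcripts of a gene. FPKM of a gene was therefore the sum over its RefSeq transcripts and over the assembled transcripts given to it from the same Cufflinks locus. At a locus with several genes, an assembled transcript went to the gene whose exons it overlapped most. It was left out where it overlapped none. At a locus with a single gene, all assembled transcripts went to that gene, and overlap with its exons was not required.

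Of 28222 RefSeq accessions, 27563 took their symbol from a RefSeq table of GRCm38.p6 (used for names alone), 82 from a GENCODE table, 300 from the files' own name, and 277 kept the accession, which gave 22708 genes. All coordinates are those of the deposited files, 1-based, in mm9. Genes were compared where FPKM was 1 or more in at least 1 library and the longest RefSeq transcript had at least 300 nt, which left 11463 genes and set aside 11245. Of the 11463, 1627 shared a Cufflinks locus with another gene, where the division of fragments is uncertain, and 762 were listed at 0 in at least 1 library. Because genes that are abundant in 1 library can be listed at exactly 0 in another, a 0 was read as listed at 0, and no fold against it is given.

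The files hold no counts, and Cufflinks values are estimates, so whole reads were not recovered. The fragments behind each library were estimated from the width of the intervals of transcripts of at least 2000 nt and 5 FPKM. They came to 62.4 M (mega) from 1376 transcripts in mock (quartiles 61.6 and 63.3). They came to 68.7 M from 1534 in the library labelled shKSRP (67.7 and 69.6) and 60.6 M from 1383 in the BMP2 library (59.8 and 61.5). The half-width for a gene is the root of the summed squares of its transcripts' half-widths, each taken from the upper bound. Transcripts were treated as independent. This half-width had a median of 3.4%, 3.2% and 3.4% of FPKM for genes at 10 FPKM or more. For genes at 1 to 10 FPKM it was 7.5%, 7.0% and 7.6%. The sum of FPKM over all genes was 677872 in mock, 533262 in the library labelled shKSRP and 564500 in the BMP2 library.

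Differences are log2((FPKM + 1)/(FPKM + 1)) between 2 libraries, with no rescaling. A gene was called higher or lower at a log2 ratio of 1 or more in size, a fixed rule of size. It is no test, since 1 library per group gives no replicate spread and no p-value. The comparisons were the library labelled shKSRP with mock, the BMP2 library with mock, the library labelled shKSRP with the BMP2 library, and the overlap of both comparisons with mock. For the overlap, the number that independent lists would share (the product of the list sizes divided by the number of genes) stands beside the observed one. So do the mean and highest of 100 simulations of unchanged libraries with the interval error alone and of 100 shuffles of each gene's values over the libraries. The median of each of 22 gene lists is given with its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins (2000 lists in the alternatives), as a description of these libraries. The members Col12a1, H19, Cd68, Hbb-b1 and Polr2a of the lists matched no symbol and were not counted in their lists. Over all lists, 13 of 208 calls of members in the library labelled shKSRP against mock, 13 of 200.0 with BMP2 against mock and 19 of 179 between these libraries rest on a gene listed at 0.

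The groups, the lists, the rule of size, the comparisons, 11 alternatives and the rule for named genes were set before the data were examined. The rule names Khsrp, the 12 genes with the highest and the 12 with the lowest ratio of each comparison (at 10 FPKM or more in 1 of the 2 libraries, with intervals apart, leaving out gene models without a proper name), up to 4 members of each list by the size of their ratio, and 10 genes of the overlap in the same and 10 in opposite directions. Genes listed at 0 in a compared library were left out of these ranks and list members, a departure from the rule, since no fold can be given, and not every gene of the rule is named. A few genes outside the rule are said to have been named after their values were seen, and Prg4, Cdc45 and Orc1 were also named that way.

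The 11 alternatives were pseudocounts of 0.1 and 5, no filter on low values, a minimum of 5 FPKM, scaling by median of ratios (factors 0.996, 0.983 and 1.005) or by the upper quartile (1.015, 0.991 and 0.994), the most abundant RefSeq transcript alone, no length minimum, 1.5-fold and 4-fold thresholds, and intervals that do not overlap. After the data were seen 6 more were added: fragments counted over a fixed gene length, assembled transcripts under 300 nt left out, genes alone in their locus, genes above 0 in all 3 libraries, both of these together, and the trend of the values over transcript length in 40 bins taken out of each library. Analyses used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. The steps were tested on simulated libraries over 11463 genes, drawn from the mock values with the interval error alone. Genes made higher were picked at 10 FPKM or more in mock, so changes of genes below that were not tested. Of these picked genes, 50 of 50 were called at each of 2.5-fold, 4-fold and 8-fold, and 1 of 50 at 1.5-fold. Of the unchanged genes, 14 of 11263 were called. Spread between libraries was not simulated, so this does not give the rate of false calls in the real libraries. Of 200 unchanged lists 10 lay outside the central 95% of random lists. A trend over length put into the simulated data left a Spearman correlation of 0.93 before and 0.03 after it was taken out.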

Results

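The data are 3 RNA-seq libraries of polyadenylated RNA from C2C12 cells, a mouse line of myoblasts that grows as mesenchymal precursors and can be turned towards muscle or towards bone. The first library came from mock-transfected cells in growth medium with 20% serum. The second came from cells in the same medium that are labelled as transfected with shKSRP, a short hairpin RNA against KSRP. KSRP is the protein of the gene Khsrp, which binds AU-rich elements in mRNAs, promotes their decay and helps the maturation of some microRNAs. The third library came from mock-transfected cells labelled DM + BMP2. For these the protocol names a differentiation medium with 2% horse serum and 100 to 300 ng/ml of BMP2, a bone morphogenetic protein that drives these cells towards osteoblasts. Each group holds 1 library, so no difference below has a replicate check and no p-value is given. The width of the deposited intervals corresponds to 62.4 M (mega) fragments in the mock library, 68.7 M in the library labelled shKSRP and 60.6 M in the BMP2 library. All values are FPKM per gene. The ± after a value is a half-width built from the upper bounds of the deposited 95% intervals of the gene's transcripts. It treats these transcripts as independent and the interval as symmetric, and it covers counting and assignment error only. Log2 ratios are of FPKM + 1, which understates the change of genes with low values. Genes are called higher or lower where the ratio passed 2-fold.

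Khsrp (chromosome 17, 57160472 to 57170930, minus strand, mm9 build) was at 31.4 ± 0.9 in the mock library, 28.4 ± 0.6 in the library labelled shKSRP and 27.1 ± 0.7 in the BMP2 library. The library labelled shKSRP thus held 90.6% of the mock value (log2 ratio −0.14), and the BMP2 library, which was mock-transfected, held 86.5% (log2 ratio −0.20). Khsrp mRNA did not separate the library labelled as a knockdown from the mock-transfected library with BMP2. Every direction given below for the library labelled shKSRP carries that doubt about its label. In the mock library 15.9 FPKM of the Khsrp total stood on an assembled transcript and 15.5 on the RefSeq transcript, so that the RefSeq transcript taken alone reverses the direction, at 15.5 in mock, 28.4 in the library labelled shKSRP and 27.1 in the BMP2 library. With a trend over transcript length taken out of each library, Khsrp in the library labelled shKSRP stood at 78.5% of mock.

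**Figure D1:**
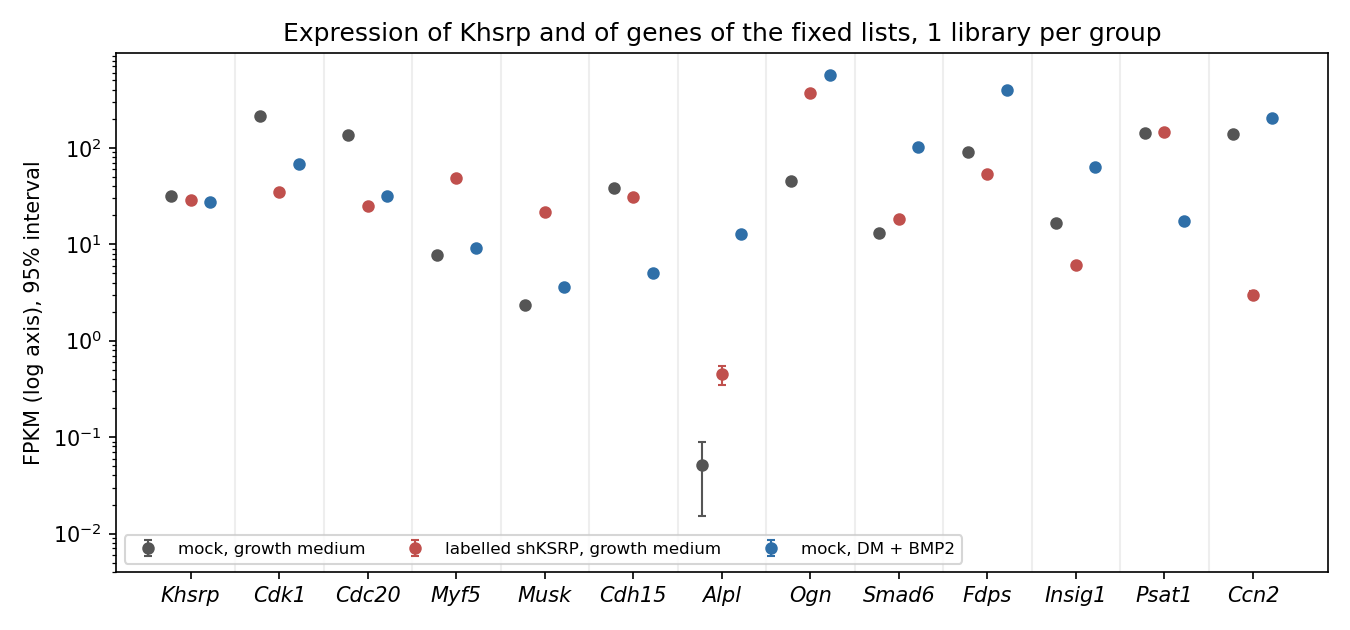
FPKM on a log axis for Khsrp and 12 genes of the fixed lists in the mock library, the library labelled shKSRP and the BMP2 library, 1 point per library, with the 95% interval as the bar. Khsrp lies between 27.1 and 31.4 in all 3 libraries, whereas Cdk1 falls from 214 in mock to 34.8 and 68.6, and Alpl is at 12.8 in the BMP2 library against 0.0518 in mock and 0.447 in the library labelled shKSRP.

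The comparison of the library labelled shKSRP with mock keeps the medium the same, and by the labels the hairpin differs. With 1 library in each group and Khsrp near mock, no difference can be credited to the hairpin. Of 53 measured genes of cell cycle and DNA replication, 46 were lower by at least 2-fold in the library labelled shKSRP, none was higher and 7 passed in neither direction. Cdk1, the kinase that starts mitosis, was at 214 ± 4.2 in mock and 34.8 ± 1.6 in the library labelled shKSRP. Cdc20, an activator of the anaphase-promoting complex, was at 137 ± 2.3 and 25.1 ± 0.93. Of 29 regulators of the muscle lineage 14 were higher, among them the determination factor Myf5 (7.75 ± 0.50 in mock and 48.4 ± 1.2) and Musk, the receptor kinase of the neuromuscular junction (2.37 ± 0.18 and 21.5 ± 0.55). Of 31 serum and immediate-early genes 15 were lower and 1 was higher, and Ccn2, which codes for connective tissue growth factor, went from 138 ± 1.9 to 2.98 ± 0.27. Among all genes, the library labelled shKSRP had 1264 higher and 1484 lower of 11463.

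Among genes above 0 in both libraries, the 12 with the highest log2 ratios of FPKM + 1 to mock included Fmod, the matrix proteoglycan fibromodulin, at 2.03 ± 0.26 in mock and 151 ± 1.8 in the library labelled shKSRP (log2 ratio 5.65). Islr, a secreted protein with leucine-rich repeats, was at 7.67 ± 0.57 and 333 ± 3.5, and Emilin1, a glycoprotein of elastic fibres, at 0.530 ± 0.099 and 37.9 ± 0.89. Enpp2, the enzyme autotaxin that makes lysophosphatidic acid, stood at 1.35 ± 0.28 in mock and 75.3 ± 1.8, and Car3, a carbonic anhydrase abundant in slow muscle, at 55.5 ± 1.9 and 1854 ± 9.8. Ncf4, a subunit of the phagocyte NADPH oxidase, went from 1.48 ± 0.53 to 238 ± 5.0. Dpyd, the enzyme that begins pyrimidine breakdown, went from 0.0996 ± 0.038 to 20.4 ± 0.51, and the interleukin-1 receptor antagonist Il1rn from 0.377 ± 0.10 to 29.1 ± 0.84. Capn6 (log2 ratio 4.08), Angpt4 (3.99) and Kremen1 (4.01) were also among these 12. With the most abundant RefSeq transcript alone the log2 ratios of Fmod, Ncf4 and Enpp2 went from 5.65, 6.59 and 5.02 to 6.40, 5.74 and 4.11.

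At the other end, the proliferin genes Prl2c3 and Prl2c2 stood at 1599.7 ± 12 and 1367 ± 12 in mock and at 20.1 ± 1.3 and 36.5 ± 1.9 in the library labelled shKSRP. The proliferins are near-identical copies at shared loci, so the division of fragments between them is uncertain. Alox5, the lipoxygenase that begins leukotriene synthesis, went from 38.7 ± 1.2 to 0.405 ± 0.092 (log2 ratio −4.82, or −4.15 with the most abundant RefSeq transcript alone). Sprr1a, a protein of the cornified envelope, went from 33.4 ± 1.8 to 0.0894 ± 0.089, and the mast cell protease gene Mcpt8 from 19.6 ± 1.3 to 0.0621 ± 0.072. Hmga1b, a chromatin protein gene that shares its locus with another gene, went from 361 ± 4.7 to 23.1 ± 1.2. Lce1g and Gzme (log2 ratios −4.48 and −4.51) share a locus too.

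Against random lists matched on expression, the cell cycle median (log2 ratio −1.51) lay at percentile 0. The myogenic median (0.63) lay at percentile 100 and the serum-gene median (−0.86) at percentile 0, as descriptions of these libraries. Cdon, a cell surface receptor of myoblasts, was at 8.96 ± 0.28 in mock and 38.6 ± 0.72 (log2 ratio 1.99, or 1.34 with the most abundant RefSeq transcript alone), and the transcription factor gene Mef2a at 2.39 ± 0.21 and 34.8 ± 0.77. The 1 myogenic gene counted as lower, Rb1, which was named after its values were seen, was at 7.34 in mock and 6.55 in the BMP2 library and listed at 0 in the library labelled shKSRP. Sarcomere genes went both ways, with 7 of 31 higher, 5 lower and a median of −0.00 (mean 0.05, percentile 42.90). The slow troponin gene Tnnt1 was at 4.53 ± 0.73 and 37.4 ± 2.0, the calcium channel subunit gene Cacng1 at 51.1 ± 2.0 and 153 ± 2.9, and the cardiac troponin gene Tnnt2, at a shared locus, at 91.2 ± 2.4 and 16.1 ± 1.1.

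AU-rich-element mRNAs and reported KSRP decay targets were 3 higher and 9 lower of 31 (median −0.59, percentile 0.29). Ctnnb1, which codes for beta-catenin, was the highest of them at 68.4 ± 1.4 in mock and 253 ± 2.4 in the library labelled shKSRP. Lower were the phosphatase gene Dusp1 (40.7 ± 1.2 and 5.07 ± 0.41), the chemokine gene Cxcl5 (43.8 ± 1.4 and 8.67 ± 0.57) and the urokinase receptor gene Plaur (123 ± 3.1 and 38.1 ± 1.7). The Plaur log2 ratio of −1.67 became −2.88 with the most abundant RefSeq transcript alone. Factors of mRNA decay and microRNA processing, a list that holds Khsrp itself, were 5 higher and 9 lower of 46 (median −0.01, percentile 58.59). Zfp36l1, another AU-rich-element binding protein, was at 10.2 ± 0.47 and 41.2 ± 0.90. Hnrnpd, which codes for AUF1 and shares its locus, was at 205 ± 4.3 and 32.5 ± 0.94, and its log2 ratio of −2.62 became −1.42 with fragments counted over a fixed gene length.

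Notch and Wnt pathway genes were 10 higher and 2 lower of 22 (median 0.93, percentile 100, and 88.05 with no filter on low values). The secreted Wnt inhibitor gene Sfrp2 was at 20.3 ± 0.82 in mock and 286 ± 2.9 in the library labelled shKSRP and Nkd2, an antagonist inside the cell, at 0.937 ± 0.15 and 24.0 ± 0.72. Genes of the extracellular matrix and its remodelling were 12 higher and 5 lower of 41 (median 0.45, percentile 100). The proteoglycan gene Bgn was at 252 ± 2.6 and 1206 ± 6.5 and the matricellular protein gene Thbs1 at 211 ± 1.8 and 1539 ± 4.8. Osteoblast and bone matrix genes were 5 higher and 4 lower of 24 (median 0.34, percentile 98.42, outside the tail in 3 of 14 alternatives). The proteoglycan gene Ogn was at 45.5 ± 1.1 and 373 ± 3.3, Col1a1 at 2.88 ± 0.23 and 15.7 ± 0.49, and the osteocalcin gene Bglap2, at a shared locus, at 23.2 ± 2.2 and 4.29 ± 1.0. BMP and SMAD target genes were 4 higher and 4 lower of 29 (median −0.33, percentile 5.49), with the homeobox gene Dlx3 at 14.5 ± 0.60 and 4.03 ± 0.30.

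Cholesterol genes were 2 higher and 6 lower of 24 (median −0.53, percentile 0.37). Of the 6, Fdft1 and Tm7sf2, named after their values were seen, were listed at 0 in the library labelled shKSRP. Insig1, a brake on sterol synthesis, was at 16.6 ± 0.64 and 6.06 ± 0.37. With the most abundant RefSeq transcript alone, or with a pseudocount of 5, the cholesterol median no longer lay in the lower tail. The interferon genes had 4 higher and 1 lower of 18 (median 0.28, percentile 85.97) and the stress genes 3 and 3 of 32 (0.04, percentile 93.29). The p53 target genes had 1 and 4 of 22 (−0.10, percentile 39.48) and the imprinted growth genes 4 and 0 of 11 (0.36, percentile 89.62). Of these 4, Mest and Peg3, named after their values were seen, were listed at 0 in mock, and Peg3 stood at 25.0 ± 54.6 in the library labelled shKSRP. Of genes of other cell types, 2 of 3 epithelial markers were lower (median −2.57, percentile 0.38), and Krt14, at a shared locus, was at 114 ± 2.7 and 18.4 ± 1.0. Neural and glial markers were 1 higher and 4 lower of 9, with a median of 0.20 and a mean of −0.84 (percentile 80.68). Tubb3, at a shared locus, was at 98.0 ± 2.0 and 9.83 ± 0.59. Blood and endothelial markers were 1 higher and 1 lower of 5 (median −0.21, mean 0.05, percentile 28.91), chondrocyte genes 0 and 2 of 4 (−0.52, percentile 9.62) and adipocyte genes 2 and 2 of 12 (0.14, percentile 68.05).

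Log2 ratios in this comparison rose with transcript length, from a median of −0.55 for 908 genes with a longest transcript under 1000 nt to 0.46 for 1177 genes over 6000 nt (Spearman correlation across genes 0.37, genes not being independent replicates). With that trend taken out of each library, an alternative chosen after the data were seen, the matrix median went from 0.45 to 0.16 (percentile 94.22), the osteoblast median from 0.34 to 0.20 (percentile 88.15) and the Notch and Wnt median from 0.93 to 0.50 (percentile 99.85). Ribosomal protein genes, whose transcripts are short, went from a median of −0.53 (0 higher, 3 lower of 38, percentile 24.51) to 0.01, and the reference genes from −0.35 (0 higher, 1 lower of 23, percentile 54.70) to −0.04. The cell cycle median stayed at −1.50 and the myogenic median went to 0.87. The sarcomere median went from −0.00 to 0.31 (percentile 96.12), and the sign changed for the neural and glial median (0.20 to −0.21, percentile 23.35) and the blood and endothelial median (−0.21 to 0.37, percentile 78.20). Of the called genes 230 of the higher and 309 of the lower were listed at 0 in 1 of the compared libraries, and among the 10701 genes above 0 in all 3 libraries 1020 were higher and 1161 lower.

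**Figure D2:**
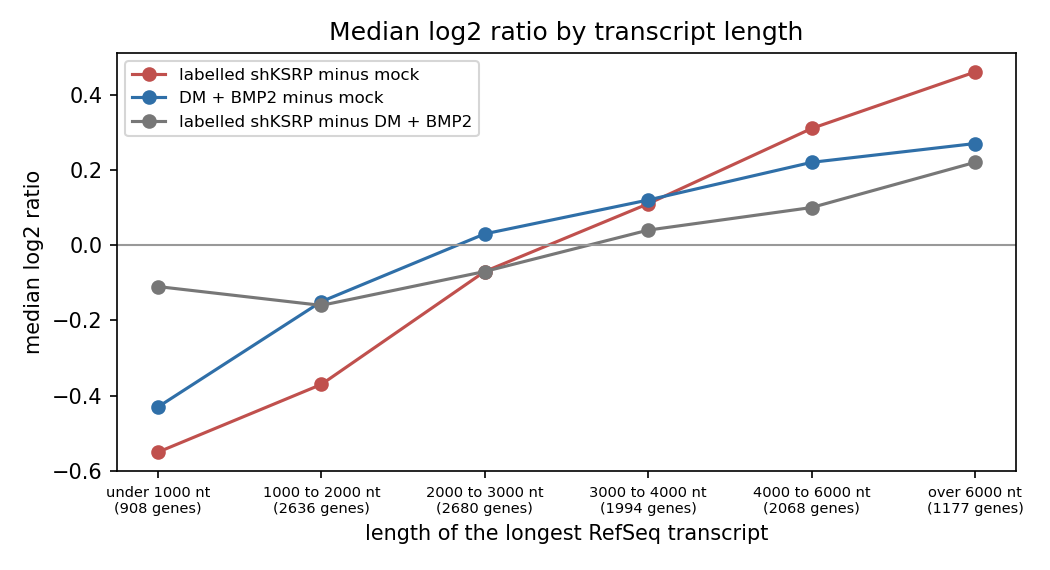
Median log2 ratio of FPKM + 1 for 6 classes of longest RefSeq transcript, with 1 line per comparison and the number of genes in brackets. The line for the library labelled shKSRP, whose Khsrp value was near mock, goes from −0.55 to 0.46, that for the BMP2 library from −0.43 to 0.27, and that between these libraries from −0.11 to 0.22.

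The comparison of the BMP2 library with mock changes, by the title of the sample, the medium and BMP2 together, so a difference belongs to their combination. The source label of that sample names BMP2 and not the medium, and its description names neither. How long these cells were treated is not settled by the labels. Osteoblast and bone matrix genes were 13 higher and 1 lower of 24 in the BMP2 library. The lower gene, Spp1, which codes for osteopontin and was named after its values were seen, went from 987 ± 6.9 to 471 ± 4.8, and with the length trend taken out the list held no lower gene. Alpl, the alkaline phosphatase of bone (chromosome 4, 137297647 to 137352292), was at 0.0518 ± 0.037 in mock and 12.8 ± 0.82 with BMP2. The proteoglycan gene Omd was at 7.99 ± 0.55 and 119 ± 2.5, and Ogn at 45.5 ± 1.1 and 563 ± 4.8. Of 29 BMP and SMAD target genes 15 were higher and none lower, among them Smad7 (4.97 ± 0.32 and 27.9 ± 0.64), which codes for an inhibitory SMAD, and the transcription factor gene Hey1 (6.05 ± 0.55 and 51.4 ± 1.6). Cell cycle genes were 48 lower of 53 with none higher. Genes of cholesterol synthesis and uptake were 16 higher of 24 with none lower, such as Fdps, an enzyme of the mevalonate pathway, at 90.0 ± 2.3 and 394 ± 4.8. Among all 11463 genes, 1056 were higher and 1026 lower.

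Among genes above 0 in both libraries, the 12 with the highest log2 ratios of FPKM + 1 included Prelp, a leucine-rich proteoglycan gene at a shared locus, at 16.3 ± 0.67 in mock and 467 ± 2.9 with BMP2 (log2 ratio 4.76). Sfrp2 went from 20.3 ± 0.82 to 395 ± 3.7, Kremen1, a receptor of the Wnt inhibitor Dickkopf, from 5.13 ± 0.32 to 108 ± 1.5, and Nkd2 from 0.937 ± 0.15 to 23.1 ± 0.61. Fmod stood at 51.6 ± 1.1 with BMP2, and C1qtnf1 went from 2.38 ± 0.23 to 37.6 ± 0.94. Enc1 went from 9.13 ± 0.42 to 122 ± 1.8. Scd1, the stearoyl-CoA desaturase, went from 39.96 ± 0.74 to 546 ± 3.3, but its log2 ratio of 3.74 became 0.69 with the most abundant RefSeq transcript alone. With that alternative the log2 ratios of Prelp, Fmod, Kremen1, C1qtnf1 and Alpl went from 4.76, 4.12, 4.16, 3.52 and 3.71 to 5.69, 4.86, 3.14, 2.64 and 2.86.

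Of the genes above 0 in both libraries the lowest included the proliferin genes Prl2c2 (1367 ± 12 and 46.7 ± 2.4) and Prl2c3 (1599.7 ± 12 and 70.1 ± 2.9). Gsta1, a glutathione transferase, went from 31.7 ± 1.7 to 1.14 ± 0.32, Mcpt8 from 19.6 ± 1.3 to 0.886 ± 0.29 and the growth factor gene Areg from 22.4 ± 1.1 to 1.43 ± 0.29. Arhgap22 and Cst6 had log2 ratios of −3.47 and −3.26, which became −2.86 and −2.04 with fragments counted over a fixed gene length and −2.37 and −1.66 with the most abundant RefSeq transcript alone.

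The medians of the osteoblast list (log2 ratio 1.10), the BMP target list (1.07) and the cholesterol list (1.59) each lay at percentile 100 of matched random lists, and that of the cell cycle list (−1.63) at percentile 0. Col1a1, which codes for a chain of type I collagen, was at 2.88 ± 0.23 and 31.9 ± 0.87. Tcf7, which also stands on the Notch and Wnt list, was at 3.8 ± 0.38 and 32.1 ± 1.1. Bub1, a kinase of the spindle checkpoint, was at 50.8 ± 1.9 and 8.84 ± 0.50 (log2 ratio −2.40, or −1.70 with a fixed gene length), and Ube2c, a ubiquitin-conjugating enzyme of mitosis at a shared locus, at 231 ± 4.3 and 42.5 ± 1.9. The sterol dehydrogenase gene Nsdhl was at 16.3 ± 1.0 and 65.6 ± 1.8.

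Sarcomere genes were 9 higher and 3 lower of 31 (median 0.76, percentile 100). The light chain gene Myl1 was at 9.81 ± 1.0 and 33.3 ± 1.9 and Ldb3, a protein of the Z-disc, at 4.51 ± 0.29 and 15.6 ± 0.58. Myogenic regulators were 3 higher and 3 lower of 29, with a median of 0.20 and a mean of −0.10 (percentile 88.52). Of these calls, 2 of sarcomere genes and 1 of a myogenic regulator rest on a gene listed at 0. The cadherin gene Cdh15 was at 38.3 ± 0.93 and 5.02 ± 0.34, the integrin gene Itga7 at 90.1 ± 1.2 and 35.9 ± 0.76, and Mef2a at 2.39 ± 0.21 and 15.0 ± 0.54. Genes of the extracellular matrix were 13 higher and none lower of 41 (0.60, percentile 100), with Thbs1 at 211 ± 1.8 and 1900.1 ± 7.7 and Col6a1 at 43.7 ± 1.1 and 201 ± 2.4. With the most abundant RefSeq transcript alone their log2 ratios went from 3.17 and 2.18 to 1.43 and 3.02. Notch and Wnt genes were 9 higher and 1 lower of 22 (0.86, percentile 100). Of 4 measured chondrocyte genes 3 were higher (2.77, percentile 100, and 95.60 with no filter on low values). Among them Prg4 was listed at 0 in both other libraries and at 42.0 with BMP2, and Col2a1, which codes for type II collagen, was at 6.95 ± 0.36 and 68.8 ± 1.2.

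Stress and unfolded protein response genes were 10 lower and none higher of 32 (median −0.22, percentile 14.26). Psat1 and Phgdh, enzymes of serine synthesis, were at 143 ± 2.3 and 248 ± 3.0 in mock. They were at 17.4 ± 0.74 and 41.6 ± 1.2 with BMP2. Chac1, which degrades glutathione, was at 39.2 ± 1.3 and 5.08 ± 0.48. Of 22 p53 target genes 2 were higher and 3 lower (−0.57, percentile 0.01). The stress protein gene Sesn1 was at 8.99 ± 0.52 and 27.5 ± 0.92 and Gtse1, which is also tied to mitosis, at 30.8 ± 0.86 and 8.23 ± 0.54. Ribosomal protein genes were 1 higher and 6 lower of 38 (−0.74, percentile 0), and with the length trend taken out their median was −0.30 at percentile 0.50, with 1 higher and 1 lower.

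Serum and immediate-early genes were 1 higher and 6 lower of 31 (−0.19, percentile 6.13), and AU-rich-element mRNAs 2 higher and 4 lower of 31 (−0.10, percentile 31.28). In the latter the prostaglandin synthase gene Ptgs2 was at 16.9 ± 0.51 and 44.2 ± 0.96, a ratio under the threshold with the most abundant RefSeq transcript alone, and the chemokine gene Ccl2 at 31.0 ± 1.7 and 5.25 ± 0.72. Decay and microRNA factors were 4 higher and 7 lower of 46 (−0.07, percentile 22.17), imprinted genes 1 and 0 of 11 (0.72, percentile 99.69, and 80.7 with the most abundant RefSeq transcript alone), interferon genes 2 and 3 of 18 (−0.11, percentile 14.59) and adipocyte genes 2 and 1 of 12 (0.14, percentile 64.79). Of markers of other cell types, epithelial genes were 1 and 1 of 3 (median 0.14, mean −1.04, percentile 61.62), neural and glial genes 0 and 4 of 9 (−0.11, percentile 27.22) and blood and endothelial genes 1 and 1 of 5 (−0.16, percentile 18.40). Of the 3 lower interferon genes 2 were listed at 0 in the BMP2 library, as were the 1 lower epithelial and the 1 lower blood and endothelial gene. Among the decay and microRNA factors 1 call rests on a 0. None of the 23 reference genes passed in either direction (−0.22, percentile 55.02). The trend over transcript length was present here too (Spearman correlation across genes 0.27). With it taken out, sarcomere genes were 15 higher and 2 lower and myogenic regulators 1 higher and 4 lower. The median of the decay and microRNA factors went to −0.23 (percentile 1.0) and that of the serum genes to −0.25 (percentile 1.5). The sign changed for the medians of the AU-rich-element mRNAs (0.06), interferon genes (0.17), adipocyte genes (−0.02) and blood and endothelial genes (0.02). Among genes above 0 in all 3 libraries 819 were higher and 767 lower.

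**Figure D3:**
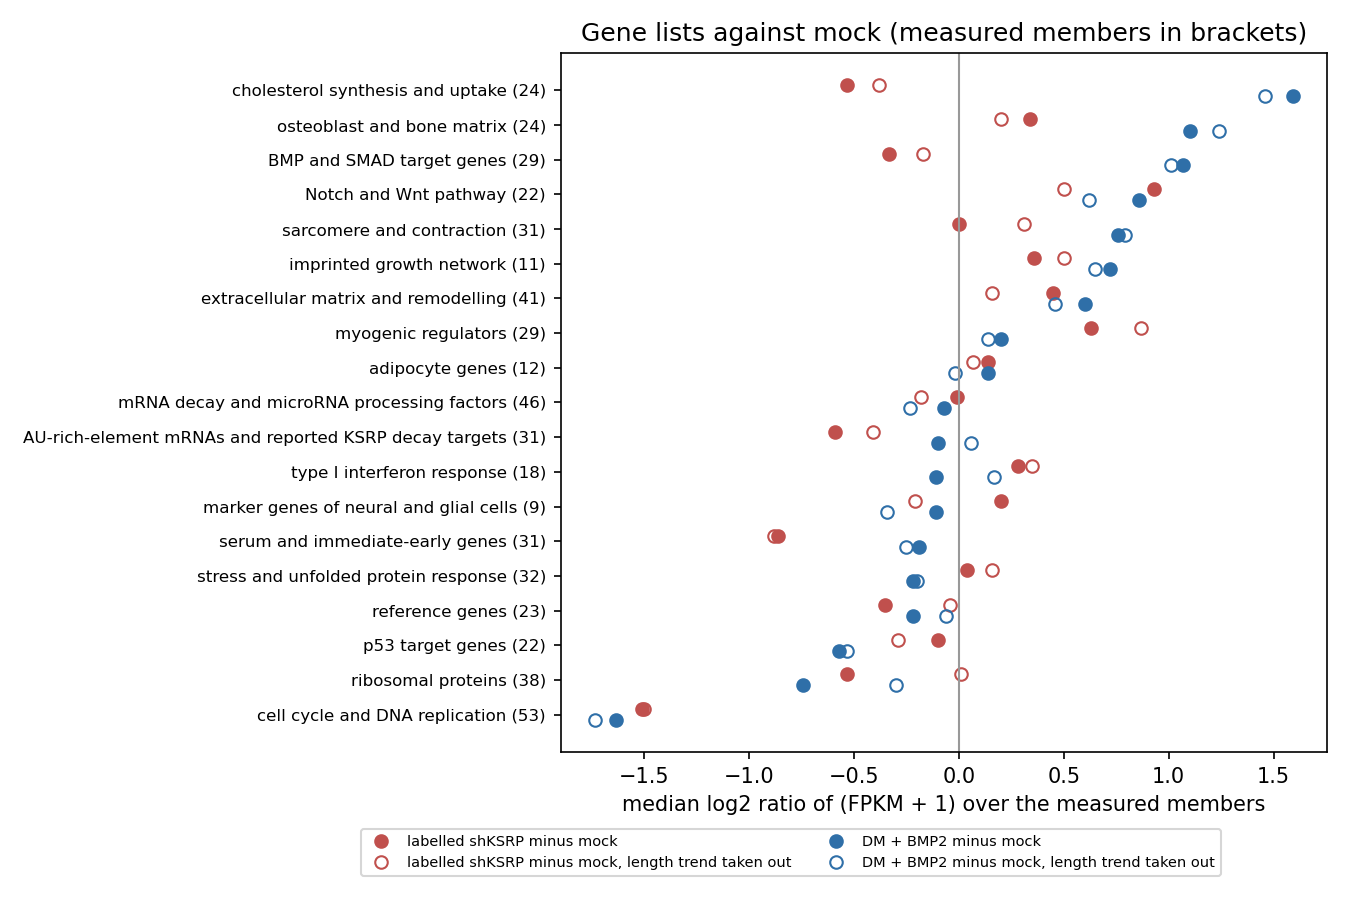
Median log2 ratio of FPKM + 1 over the measured members of the 19 lists with at least 9 of them, for the library labelled shKSRP (Khsrp near mock) and the BMP2 library against mock, with open circles for the values after the length trend was taken out. Cell cycle genes stand lowest in both (−1.51 and −1.63), and the cholesterol list stands at −0.53 and 1.59.

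The direct comparison of the library labelled shKSRP with the BMP2 library does not use the mock library. By their labels these libraries differ in the transfection, the medium and BMP2 together, so a difference belongs to their combination. Cholesterol genes were lower in the library labelled shKSRP, 20 of 24 with none higher (median −1.79, percentile 0). Of the 20, Fdft1, Tm7sf2 and Acat2, named after their values were seen, were listed at 0 in the library labelled shKSRP. Insig1 was at 6.06 ± 0.37 against 63.0 ± 1.3 in the BMP2 library and Fdps at 53.2 ± 1.7 against 394 ± 4.8. BMP and SMAD target genes were 1 higher and 17 lower of 29 (−1.17, percentile 0). Smad6, an inhibitory SMAD, was at 18.1 ± 1.1 against 102 ± 2.5 (log2 ratio −2.44, or −3.18 with the most abundant RefSeq transcript alone) and Hey1 at 7.38 ± 0.45 against 51.4 ± 1.6. Myogenic regulators were 13 higher and 1 lower of 29 (0.88, percentile 100). Myf5 was at 48.4 ± 1.2 against 9.09 ± 0.54 and Musk at 21.5 ± 0.55 against 3.59 ± 0.22. Among 11463 genes, 696 were higher and 993 lower in the library labelled shKSRP, whose Khsrp value was 28.4 ± 0.6 against 27.1 ± 0.7.

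Osteoblast genes were 2 higher and 10 lower of 24 (−0.91, percentile 0), with Omd at 9.39 ± 0.68 in the library labelled shKSRP against 119 ± 2.5, and Cdh11, a cadherin of osteoblasts, the other way at 22.2 ± 0.67 against 2.00 ± 0.24 (log2 ratio 2.95, or 1.97 with the most abundant RefSeq transcript alone). Sarcomere genes were 4 higher and 14 lower of 31 (−0.69, percentile 0), with the embryonic myosin gene Myh3, at a shared locus, at 0.168 ± 0.040 against 3.49 ± 0.23. Serum and immediate-early genes were 1 higher and 12 lower of 31 (−0.74, percentile 0). Ccn2 was at 2.98 ± 0.27 against 205 ± 2.4 and Dusp1 at 5.07 ± 0.41 against 69.9 ± 1.8. All 4 chondrocyte genes were lower (−3.93, percentile 0.01). Of the 4, Prg4 was listed at 0 in the library labelled shKSRP, and the median rests in part on that 0. Col2a1 stood at 0.0556 ± 0.025 against 68.8 ± 1.2 (log2 ratio −6.05, or −4.57 with the most abundant RefSeq transcript alone). Stress genes were 11 higher and 2 lower of 32 (0.23, percentile 99.86, and 88.1 with the most abundant RefSeq transcript alone), with Asns, the asparagine synthetase, at 147 ± 2.5 against 23.1 ± 1.1 and the amino acid transporter gene Slc7a5 at 69.7 ± 1.4 against 7.54 ± 0.49.

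Of the genes above 0 in both libraries, the 12 highest included Dpyd (20.4 ± 0.51 against 0.110 ± 0.040), the hormone gene Fgf21 (14.7 ± 1.1 against 0.141 ± 0.11), the iron exporter gene Slc40a1 (25.8 ± 0.67 against 1.21 ± 0.18) and the Wnt ligand gene Wnt10a (21.4 ± 0.81 against 0.883 ± 0.20). Pvalb, a calcium buffer of fast muscle, was at 15.5 ± 1.2 against 0.194 ± 0.13. The 12 lowest of these genes included the peptide hormone gene Cck (0.0269 ± 0.054 against 25.6 ± 1.8), Serping1, the C1 inhibitor (0.176 ± 0.077 against 18.5 ± 0.84), and Krt14 (18.4 ± 1.0 against 264 ± 3.3).

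Matrix genes were 5 higher and 11 lower of 41 (−0.30, percentile 1.4), a direction that reversed with the most abundant RefSeq transcript alone (0.19). The protease inhibitor gene Timp3 was at 14.7 ± 0.42 against 118 ± 1.5. Cell cycle genes differed little, with 3 higher and 1 lower of 53 (0.17, percentile 99.62, and 49.3 with the most abundant RefSeq transcript alone). Of the 3, Cdc45 and Orc1 were listed at 0 in the BMP2 library and stood at 8.06 and 1.91 in the library labelled shKSRP. Cdk1 stood at 34.8 ± 1.6 against 68.6 ± 2.3, a ratio under the threshold. Notch and Wnt genes were 3 higher and 5 lower of 22 with a median of 0.28 and a mean of −0.19 (percentile 98.90), where Wnt4 was at 11.5 ± 0.42 against 93.0 ± 1.3. That percentile left the upper tail in 3 of 14 alternatives, and with the length trend taken out the median was 0.14 at percentile 84.70. AU-rich-element mRNAs were 1 higher and 9 lower of 31 (−0.37, percentile 0.24), a percentile that left the lower tail in 6 of 14 alternatives. Interferon genes were 3 higher of 18 with none lower (0.50, percentile 99.91, and 83.25 with the most abundant RefSeq transcript alone). Of these 3, Irf9 and Rtp4, named after their values were seen, were listed at 0 in the BMP2 library. Ribosomal protein genes were 1 and 1 of 38 (0.17, percentile 99.88). The p53 targets were 2 and 2 of 22 (0.04, percentile 67.73), decay factors 2 and 2 of 46 (median 0.00, mean −0.04, percentile 66.66) and adipocyte genes 3 and 2 of 12 (−0.05, percentile 42.09). Imprinted genes were 4 higher and 1 lower of 11 (median −0.38, mean 0.46, percentile 3.84), epithelial markers 0 and 1 of 3 (−0.93, percentile 3.50), neural markers 1 and 1 of 9 (median 0.67, mean −0.03, percentile 99.72) and blood and endothelial markers 1 and 2 of 5 (0.76, percentile 96.80). The neural median reversed with the most abundant RefSeq transcript alone (−0.58) and with a fixed gene length (−0.53). The 23 reference genes held none in either direction (−0.06, percentile 66.06, and a median of 0.05 with the length trend taken out). Among genes above 0 in all 3 libraries 493 were higher and 723 lower.

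Genes changed in the same direction in both comparisons with mock were set against the number that independent lists of those sizes would share. Higher in both were 522 genes (116.4 for independent lists) and lower in both 688 (132.8), while 45 were called in opposite directions (249.8). A gene listed at 0 in mock alone can be called higher in both. Among genes above 0 in all 3 libraries, 378 were higher in both, 522 lower in both and 23 opposite. In both, Sfrp2, Kremen1, Nkd2, C1qtnf1 and Fmod were higher and Prl2c2, Prl2c3 and Mcpt8 lower. In opposite directions stood Col2a1, Insig1, the Notch modifier gene Lfng (35.0 ± 1.0 in mock, 13.4 ± 0.59 in the library labelled shKSRP, 99.0 ± 1.7 with BMP2) and Lgr6, a receptor of R-spondins (7.64 ± 0.41, 1.37 ± 0.19 and 24.8 ± 0.73). Aldh1l2, an enzyme of mitochondrial folate metabolism, stood at 10.7 ± 0.47, 32.9 ± 0.56 and 1.70 ± 0.13, and Cth, which makes cysteine, at 3.06 ± 0.34, 16.6 ± 0.94 and 0.651 ± 0.16. Of these, the calls of Aldh1l2 with BMP2 and of Cth in the library labelled shKSRP ended with the most abundant RefSeq transcript alone.

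The log2 ratios of both comparisons correlated across genes with r = 0.616 (covariance 0.701), genes not being independent replicates, and 73.8% of genes had the same sign. Both share the mock library, and unchanged libraries simulated with the interval error alone gave a mean r of 0.498 (highest of 100, 0.778) with a covariance of 0.004 (highest 0.009), so the covariance exceeded the mean by 0.697. They held means of 2.1 genes higher in both, 1.8 lower in both and 0.5 opposite (highest 6, 6 and 3). Shuffling each gene's 3 values over the libraries, which leaves no library special, gave means of 389.4 genes higher in both, 480.6 lower in both, 55.4 opposite and r = 0.501 with a covariance of 0.532. The highest of 100 shuffles were 434, 549, 71, 0.539 and 0.588 in the same order. The observed covariance exceeded the mean of the shuffles by 0.169. Shuffled libraries share a control as well. Most of the excess over independent lists, and most of the shortage of opposite genes, thus arose with no library special. With 1 mock library the control could not be split, and part of the remainder may come from it too.

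**Figure D4:**
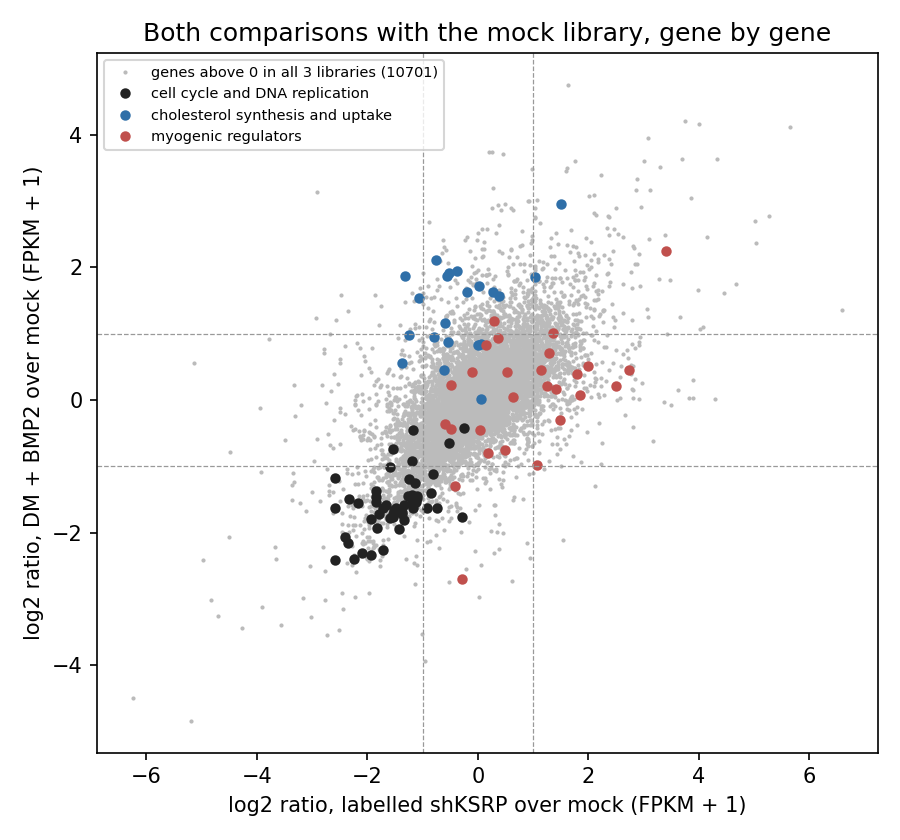
Log2 ratio of FPKM + 1 of the BMP2 library over mock against that of the library labelled shKSRP (Khsrp near mock) over mock, 1 point per gene for the 10701 genes above 0 in all 3 libraries, with dashed lines at the 2-fold threshold and 3 fixed lists in colour. Cell cycle genes lie low on both axes (list medians −1.51 and −1.63), cholesterol genes high on the BMP2 axis alone (−0.53 and 1.59) and myogenic regulators towards the right (0.63 and 0.20).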

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

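The tests of Khsrp and of the shared direction, and the last test of the genes listed at 0, were chosen after the results were seen, whereas the other 2 tests of the genes listed at 0 were written before their results were known.

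Data outside the comparisons drew attention because they held signal with none over it in mock. In the library labelled shKSRP, whose Khsrp value was near mock, 309 spliced assembled transcripts without a RefSeq gene stood at 1 FPKM or more. Of these 309, 23 had no transcript over them in mock. In the BMP2 library 18 of 367 such transcripts had none over them in mock. The highest of the 23 was at 9.50 ± 1.42 FPKM (chromosome 11, 93994844 to 94017078, plus strand, 433 nt in 4 exons, mm9). The highest of the 18 was at 3.09 ± 1.03 FPKM (chromosome 3, 60097265 to 60123110, minus strand, 350 nt in 3 exons).

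Khsrp stood at 90.6% of mock in the library labelled shKSRP. A different split of transcript models is argued against by fragments counted over a fixed gene length (90.0% of mock). Scaling by median of ratios left Khsrp at 91.7% of mock, which argues against library scaling as the cause. Removal of the length trend lowered it to 78.5%. The bound for that value was set after it was seen, so it does not decide whether the trend hid part of a reduction. An exchange with the BMP2 library is argued against by the BMP and SMAD target genes, with a median log2 ratio of −1.17 between these libraries. Little knockdown of the mRNA in these cells, a knockdown seen in protein alone, and a wrong label of this library cannot be told apart, since protein was not measured and the group holds 1 library at 90.6%. A biological effect of KSRP on the genes of this comparison may exist and was not tested apart from the label.

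The comparisons with mock moved together, with a covariance of 0.701 between their log2 ratios. Counting and assignment error of the shared mock library gave a covariance of at most 0.009 in 100 simulations, which argues against it as the whole cause. Removal of the length trend left 90.0% of the covariance, which argues against the trend as the whole cause. A mock library unlike other mock libraries and a response common to the library labelled shKSRP and the BMP2 library cannot be told apart, because there is 1 mock library. Shuffled values, with no library special, gave r = 0.501. Sharing the mock library sets that r by construction, so it decides nothing between these explanations. Among 3919 genes called in at least 1 comparison the mock library stood apart in 1789 (45.6%), the library labelled shKSRP in 1336 (34.1%) and the BMP2 library in 794 (20.3%).

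Of the 11463 genes, 148 were listed at 0 in at least 1 library and at 20 FPKM or more in another, such as Anapc10, Araf, Arpc5l and Eif2b4, which were named after their values were seen. Fragments given to another transcript were looked for as a transcript at 1 FPKM or more that covered at least 50% of the gene. It had to lie on the same strand or have no strand given. Of the 148, 4.1% lay under such a transcript in every library at 0, where over 60% had been set as the bound for that explanation. Of genes at 20 FPKM or more in all libraries 1.6% did. This argues against such covering transcripts for most of the 148. Transcripts on the other strand or with less overlap were not counted, so a loss of fragments to these is not decided. Transcripts of the same gene stood at several places for 0.7% of the 148, beside 0.3% of the genes at 20 FPKM or more in all libraries. That measure cannot decide on near-identical copies, since it misses copies with names of their own, such as Prl2c2 and Prl2c3. Of 220 pairs of a gene and a library under 1 FPKM with 20 FPKM or more in another library, 88.2% were at exactly 0. The other 26 pairs lay between 0 and 1, in a test devised after the first had failed. A candidate explanation is that no estimate was made for these genes in that library. The pairs at exactly 0 are those of the 148 genes themselves, so this share describes the pattern and does not decide on that explanation. Whether an estimate is missing, and for what reason, stays open, and 41.2% of the 148 shared a locus, beside 16.6% of 3251 genes at 20 FPKM or more in all libraries.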

How the results depend on the processing

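Of the alternatives, 6 were added after the data were seen (fixed gene length, short assembled transcripts left out, genes alone in their locus, above 0 in all 3 libraries, both of these, length trend taken out), and the other 11 were planned. Of the counts, 114 values lay within 1.5 times the reported ones and 39 moved further. List medians and named genes count as moved beyond the error of the deposited intervals. Of the list medians 603 stayed, 303 moved and 3 reversed, and of the values of named genes 1355, 1221 and 18. A change of sign counted as reversed where the main ratio passed 2-fold, for Khsrp at any ratio, and where the main list median lay outside the central 95% of random lists. Besides these, 8 values of named genes and 35 list medians changed sign. The correlation of the comparisons with mock ranged from 0.587 (pseudocount 0.1) to 0.645 (pseudocount 5). With 1 library per group, depth limits the counting error of single values, and no setting replaces a replicate. No paired analysis was possible because each group holds 1 library. Except for the thresholds, the pseudocounts and the alternatives that remove genes, where fewer or more genes pass by construction, the cause was not tested.

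With a 1.5-fold threshold the library labelled shKSRP had 2470 genes higher and 2771 lower than mock, the BMP2 library 2229 and 2112, and the library labelled shKSRP 1524 and 2013 against the BMP2 library. Higher than mock in both were 1242, lower 1448 and opposite 222. With a 4-fold threshold these numbers were 333 and 395, 297 and 263, 228 and 320, and 148, 140.0 and 3. With a pseudocount of 5 they were 605 and 909, 540.0 and 628, 335 and 514, and 229, 410.0 and 17. A pseudocount of 0.1 gave 146 opposite genes.

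Among genes alone in their locus and above 0 in all 3 libraries, 678 were lower with BMP2 than in mock, 446 higher and 635 lower in the library labelled shKSRP than in the BMP2 library, 333 higher and 458 lower in both comparisons with mock, and 22 opposite. Among genes above 0 in all 3 libraries 23 were opposite.

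With the most abundant RefSeq transcript alone 1906 genes were higher in the library labelled shKSRP than in mock, 1159 higher than in the BMP2 library, 929 higher than mock in both and 68 opposite. Directions between the library labelled shKSRP and the BMP2 library reversed for the median of the matrix genes (0.192) and of the neural and glial markers (−0.582, and −0.534 with a fixed gene length), and for the log2 ratios of Igf2r (−0.50), Hmgb2 (−0.59), Cenpa (0.01), Fubp1 (−0.08), Rpl37 (0.80, and 1.36 with short assembled transcripts left out) and Rpl28 (−0.68). Against mock they reversed in the library labelled shKSRP for Khsrp (0.83), Igf2r (−0.32) and Hsp90b1 (0.24). With BMP2 they reversed for Khsrp (0.77), Myc (0.51), Aurka (0.34), Rpl37 (−1.52, and −1.52 with short assembled transcripts left out), Rps6 (0.89), Mylpf (−0.37) and Phlda1 (0.10).

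The log2 ratios of Khsrp to mock were −0.10 in the library labelled shKSRP and −0.17 with BMP2 under upper-quartile scaling, and −0.35 and −0.39 with the length trend taken out. Between these libraries the ratio was 0.10 under median-of-ratios scaling.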

Other observations

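The values are given without a test or an explanation, for genes of the fixed lists except where they are said to have been named after their values were seen.

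A noncoding transcript that kept its RefSeq accession NR_001592, known as that of H19, was named after its values were seen and is not counted in the imprinted list (chromosome 7, 149761437 to 149764051, minus strand, mm9). It was at 430.7 ± 4.9 FPKM in mock, 1596 ± 9.3 in the library labelled shKSRP (Khsrp near mock) and 394 ± 4.7 with BMP2. Of the imprinted growth genes, Peg10, which derives from a retrotransposon, was at 12.1 ± 0.34, 19.8 ± 0.41 and 37.3 ± 0.60 in the same order. The zinc finger gene Zim1 was at 0.191 ± 0.059, 3.85 ± 0.25 and 0.389 ± 0.076. Lpl, the lipoprotein lipase, was at 6.70 ± 0.32, 23.6 ± 0.58 and 9.95 ± 0.40, whereas Angptl4, which codes for an inhibitor of that enzyme, was at 37.4 ± 1.1, 14.6 ± 0.68 and 6.30 ± 0.48. Pmaip1, a p53 target that promotes apoptosis, was at 6.93 ± 0.41, 1.35 ± 0.17 and 3.70 ± 0.30.

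Of interferon-induced genes, Irgm1, a GTPase, was at 7.22 ± 0.58, 27.5 ± 0.95 and 18.0 ± 0.91 FPKM in mock, the library labelled shKSRP and the BMP2 library, and the ubiquitin-like Isg15 at 1.97 ± 0.45, 5.37 ± 0.71 and 1.60 ± 0.41. Rapsn, which gathers acetylcholine receptors at the synapse and was named after its values were seen, was at 31.3 ± 1.1 and 76.1 ± 1.7 in mock and the library labelled shKSRP and listed at 0 in the BMP2 library. The acetylcholine receptor gene Chrnb1 was at 10.8 ± 0.61, 23.7 ± 0.81 and 4.94 ± 0.40.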
